A study of Mus musculus with 6 samples.

How the data were processed

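RNA was measured in skeletal muscle stem cells (satellite cells) of C57BL/6 mice. Per the labels, 3 libraries came from cells fixed with 0.5% paraformaldehyde for 30 minutes at 4 °C after isolation, and 3 from live, unfixed cells. Paraformaldehyde crosslinks proteins and nucleic acids. The labels give the same fixation and extraction text for all 6 samples, a kit made for formalin-fixed tissue with a changed protease step, so they do not state separately how RNA of the unfixed cells was extracted. Libraries were made with a stranded low-input total RNA kit and sequenced as 65-bp single-end reads on a HiSeq 2500, per the labels' protocols. A total RNA kit does not select polyadenylated transcripts, so nuclear, unspliced and small structural RNA can be counted. Nothing in the labels says whether the samples came from separate animals or isolations, so p-values measure the spread between these samples, which may be technical.

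The authors deposited 1 table of whole-number read counts per Ensembl gene for the 6 libraries, not normalized, with no gene symbols. The submitters' processing notes name cutadapt 1.11, STAR 2.5.0a, featureCounts 1.4.6-p3, R 3.3.1, DESeq2 1.12.3 and build GRCm38, with no role or order. The counted feature, the strand setting, the treatment of reads with several alignments and any removal of duplicates are not given in the sources used here. All 6 columns were matched to samples by name. Totals were 63674002, 62682196 and 20709602 counts for unfixed a, b and c, and 54225418, 76799920 and 40154441 for fixed a, b and c. Within each group every pair of libraries differed by more than sampling noise, with chi-square per degree of freedom between 21.1 and 78.1.

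Symbols, classes, positions, lengths and GC content came from the GENCODE annotation of GRCm38, matched by identifier without its version for 48349 of 48709 genes. What the table counts was tested on the table itself. Of 4552 genes lying in introns of a gene on the same strand, 99.3% had 0 counts in all 6 libraries. Of 3780 lying in introns of a gene on the opposite strand only, 98.3% had 0 counts, against 13.4% of 26661 genes that overlap no other. A 0 for a gene inside another gene therefore says nothing about its expression, partly overlapping genes can be undercounted, and intronic reads can enter the counts of long genes. All 37 mitochondrially encoded genes were at 0 in every library, so mitochondrial transcripts could not be compared. Genes with near-identical copies (histones, globins, ribosomal protein genes, Gapdh, Hspa1a) are uncertain for the same reason of read assignment.

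The main test was the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05, on all 6 libraries without a replicate block. It covered 21717 genes. Standard errors of fold changes came from a limma-voom fit (limma 3.58.1), since edgeR gives none. Equality within 2-fold was tested with a pair of one-sided limma-voom tests per gene against log2 fold changes of -1 and 1. The 30 gene lists were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured, beside camera with an estimated correlation and fry. Shares of counts and numbers of detected genes were compared by two-sided exact permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1. Detection was counted after thinning each library to the smallest total. Library correlations used log2(CPM + 1), with CPM computed here from the deposited counts.

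Named genes were those called, up to 10 per direction, with mean CPM of at least 5, no overlap between groups and no predicted-gene name. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were added and are said not to pass. Also named were the 2 to 4 most abundant members of each list and Pax7, Myf5, Myod1, Fos, Jun, Egr1, Hspa1a, Malat1, Actb and Gapdh. The tests, lists, naming rule and alternatives were fixed before the data were examined. Alternatives covered the scaling, the low-count filter, a replicate block, each library left out, removal of mitochondrial, ribosomal and small structural RNA genes, thinning, DESeq2 1.42.0, limma-voom, a 1.5-fold null, and length and GC offsets. Subtraction of a uniform background, removal of each library's trend on mean abundance with a natural spline, and the joint removal of unfixed b and fixed c were added later, after the data were seen.

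The scripts were tested on simulated counts of the real means, library sizes and dispersions with 200 changed genes. For fixed against unfixed cells, 21083 of 21717 simulated genes passed the filter and entered the fit, and the shares below are of all simulated genes, those left out by the filter included. The test recovered 2.99% of 67 genes changed 1.5-fold, 25.4% of 67 changed 2-fold and 60.6% of 66 changed 4-fold, of which 63, 65 and 60 were in the fit, with 6 calls among 20895 unchanged genes in the fit. The within-2-fold test called 13043 of the unchanged genes, 0 genes changed 2-fold and 0 changed 4-fold. The simulation draws genes independently, so it leaves out variation that many genes share. In a second simulation, also of independent genes, 1 list shifted by -0.5 on the log2 scale was called and 0 of the other lists were. It therefore does not show how the preset correlation behaves where the genes of a list vary together.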

Results

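Transcripts were counted in 6 libraries of mouse muscle stem cells, 3 from cells fixed with 0.5% paraformaldehyde and 3 from live cells. The series title names transcript quality and composition as the question. Library totals ran from 20709602 counts in unfixed c to 76799920 in fixed b. Levels below are TMM-scaled CPM as mean ± SD with n = 3 libraries per group, and log2 fold changes are fixed over unfixed.

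Of all tested genes, Trim71 alone was called between fixed and unfixed cells. Trim71, which encodes an RNA-binding ubiquitin ligase known from embryonic development, fell from 55.5 ± 20.9 CPM in unfixed cells to 3.97 ± 1.29 CPM in fixed cells. Its log2 fold change was -3.79 (SE 0.39, adjusted p = 0.041 by the edgeR quasi-likelihood test), and all 3 fixed libraries lay below all 3 unfixed ones. Trim71 (ENSMUSG00000079259.2) spans positions 114507133 to 114564369 on the minus strand of chromosome 9 in GRCm38. Raw counts over this gene were 4419, 4077 and 659 in unfixed a, b and c, and 209, 425 and 106 in fixed a, b and c, where they were 2.89, 2.97 and 4.10 times the level that the density of counts over long neuronal genes gives for its length. The call was lost without unfixed a (adjusted p = 0.111) and without fixed a (adjusted p = 0.258), in limma-voom (adjusted p = 0.134) and with total-count scaling (adjusted p = 0.069). Among other settings, it was also lost without the low-count filter and with the letters as a replicate block. Over 20 alternatives Trim71 was called in 10, its log2 fold change ran from -4.29 to -3.51 and its adjusted p from 1.12e-37 to 0.792.

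Il1rapl1, a synaptic adhesion gene of the X chromosome (ENSMUSG00000052372.10, 86740870 to 88115645, minus strand), had the smallest unadjusted p of the genes higher in fixed cells and did not pass. Its level was 101.2 ± 42.9 CPM in unfixed and 10390 ± 9169 CPM in fixed cells. The log2 fold change was 6.68 by edgeR (adjusted p = 1.00) and 5.82 by limma-voom, to which the SE of 1.32 belongs. Every fixed library lay above every unfixed one, the highest of which was unfixed b at 150.5 CPM. The fixed libraries differed widely, at 815 CPM in fixed a, 11264 in fixed b and 19090 in fixed c, and its counts in unfixed a, b and c were 2.38, 12.5 and 3.01 times the level from long neuronal genes. Without fixed a its adjusted p was 0.0017, and DESeq2 called it at an adjusted p of 5.27e-11.

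None of the other genes named by their small unadjusted p passed. Sspn, a component of the dystrophin complex, was at 10.4 ± 1.99 CPM in unfixed and 36.4 ± 25.0 in fixed cells. Rpph1, the RNA of RNase P, was at 1113 ± 186 and 1582 ± 59.8 CPM, Gapdh at 18.8 ± 3.67 and 27.9 ± 3.37, and Abhd6 at 5.24 ± 0.63 and 7.95 ± 1.1. Of the genes lower in fixed cells, Lin7c was at 67.6 ± 6.30 and 56.4 ± 3.50 CPM, Lsm14a at 104 ± 1.58 and 90.3 ± 5.93, Gas5 at 358 ± 25.3 and 307 ± 27.2, and Eif4a2 at 139 ± 2.08 and 121 ± 8.79. By edgeR, 200 genes had an unadjusted p under 0.05, 182 higher and 18 lower in fixed cells, where 1086 would be expected by chance. That count was 108 without fixed a, 114 without fixed b, 619 without unfixed a and 823 without fixed c, and 1358 without unfixed b and fixed c, where 1110 would be expected by chance. The fitted coefficient of variation within groups was 0.26 with all 6 libraries and 0.14 without unfixed b and fixed c. Other splits of the 6 libraries into 3 and 3 gave 74 to 5825 such genes. A count below the chance level therefore does not show that fixed and unfixed cells are alike. The balance of higher and lower genes depended on the fit, with 151 higher and 72 lower under length and GC offsets, 117 and 56 with the letters as a replicate block, 405 and 112 without the low-count filter and 83 and 31 without fixed b. limma-voom called 0 genes and DESeq2 4, which were Trim71, Il1rapl1, Entr1 and Gm24803. Of these, Entr1 (0.70 to 3.79 CPM over the libraries) and Gm24803 (0.015 to 3.44 CPM, the highest in fixed c) were rare. Left without unfixed b and fixed c, a choice made after the data were seen, edgeR called 12 genes, 8 higher and 4 lower, and Trim71 was not among them (adjusted p = 0.792).

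**Figure D1:**
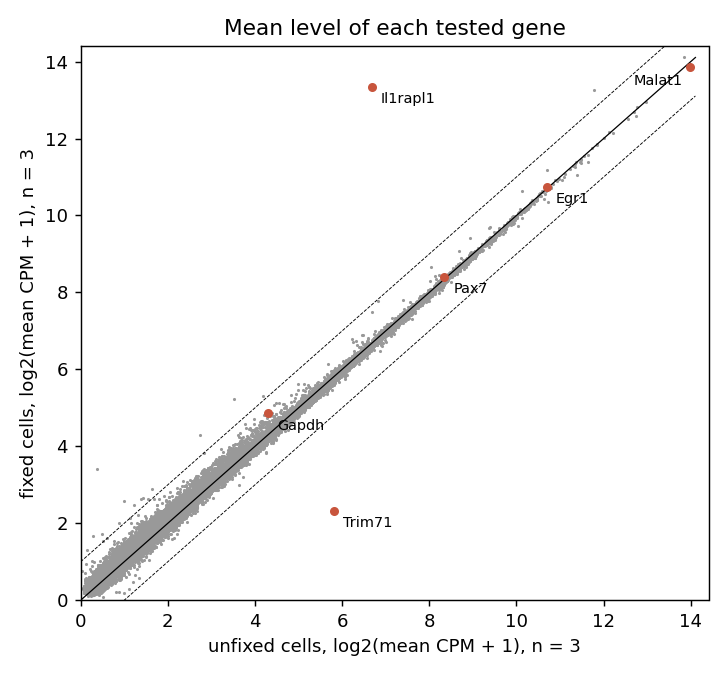
Mean level of each of 21717 tested genes in unfixed (x axis) and fixed (y axis) cells, as log2(mean CPM + 1) over 3 libraries each; the solid line marks equal levels and the dashed lines 2-fold. Trim71 (log2 fold change -3.79) lies below the lower dashed line and Il1rapl1 (6.68, not called) above the upper one, while Pax7, Egr1, Gapdh and Malat1 lie between them.

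**Figure D2:**
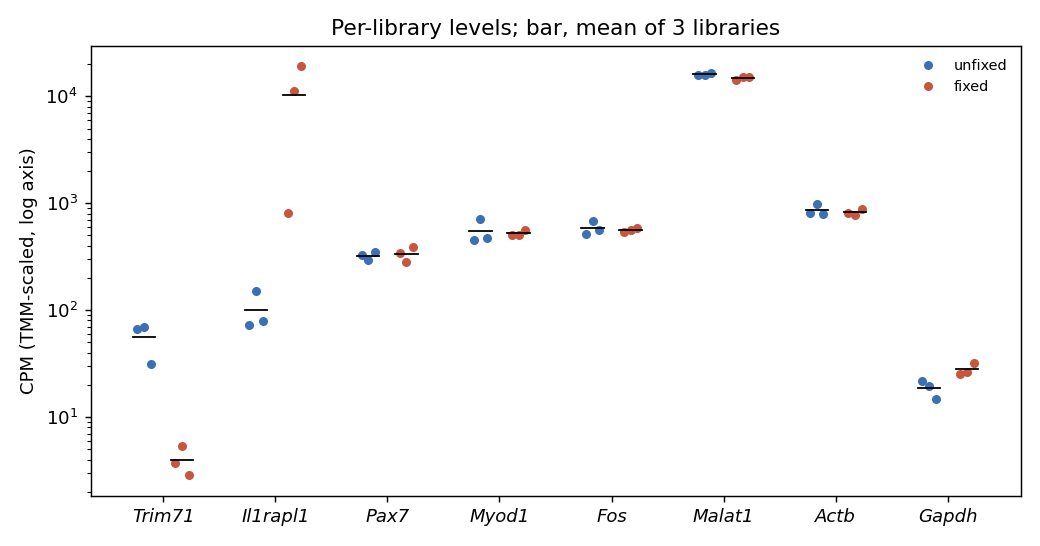
Level of 8 genes in each library in CPM on a log axis, with unfixed libraries in blue, fixed libraries in red and a bar at the mean of 3 libraries. Trim71 averaged 55.5 CPM in unfixed and 3.97 in fixed cells, and fixed a held 815 CPM of Il1rapl1 where fixed c held 19090.

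All 19 measured satellite cell markers were held within 2-fold. Pax7, the transcription factor that marks satellite cells, was at 323 ± 26.3 CPM in unfixed and 338 ± 52.7 CPM in fixed cells, and Myf5 was at 131 ± 7.4 and 120 ± 26.0. Myod1, which drives myogenic commitment, was at 546 ± 139 and 526 ± 35.9 CPM. Of 34 measured immediate early genes, which respond early to cell isolation, 33 were held within the bound. Among these were Fos at 582 ± 85.4 and 563 ± 24.9, Jun at 226 ± 54.9 and 229 ± 46.9 and Egr1 at 1657 ± 290 and 1717 ± 22.0 CPM. Actb was at 861 ± 101.3 and 824 ± 46.7 CPM, and the nuclear transcript Malat1 at 16139 ± 496 and 14937 ± 573. Hspa1a, a stress-induced chaperone with a near-identical neighbour copy, was at 65.6 ± 34.1 and 52.8 ± 29.3 CPM and was not shown to lie within 2-fold (adjusted p = 0.124).

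By the limma-voom equality test, 13393 of 21717 genes (61.7%) lay within 2-fold, and 8212 lay within 1.5-fold. The share depended on abundance. It was 7.44% of 6168 genes with a mean CPM under 1, 61.4% of 5549 genes from 1 to 5, and 99.1% of 2187 genes at 100 or more. Of 10000 genes with a mean CPM of at least 5, 9526 (95.3%) lay within 2-fold. Genes outside the count were not shown to differ: for the rarest genes the median standard error was 0.58 on the log2 scale.

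Of 28 gene lists with enough measured members, 13 were lower in fixed cells by camera with the preset correlation, 0 were higher, and 0 passed with an estimated correlation or by fry. The estimated correlation of the 13 lists ran from 0.19 (cell cycle genes) to 0.79 (endothelial markers), where the preset was 0.01. Adjusted p-values with the preset correlation are therefore too small where members of a list vary together. No member of any list was called over all genes. Adjusted over the list alone, 1 replication-dependent histone gene and 1 small structural RNA, both higher in fixed cells, passed, and no member of another list did. The shifts were small: the median log2 fold changes of the 13 lists lay between -0.17 and -0.02.

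Abundant genes as a whole were lower more often than rare ones. Over all genes 8903 of 21717 were lower, but the share was 73.6% at a mean CPM of 100 or more and 64.5% from 20 to 100, against 24.9% under 1. With the trend on abundance removed from each library, a choice made after the data were seen, 6 of the 13 lists remained lower by camera with the preset correlation. These were mitochondrial ribosomal proteins (adjusted p = 5.49e-07), oxidative phosphorylation (3.85e-06), proteasome subunits (6.20e-04), cell cycle genes (0.0017), endothelial markers (0.0063) and NF-kB genes (0.040). The other 7 no longer passed, with adjusted p-values of 0.846 for satellite cell markers, 0.882 for immediate early genes, 0.1004 for heat shock genes, 0.577 for NRF2 and extracellular matrix genes, 0.0503 for the unfolded protein response and 0.410 for cytosolic ribosomal proteins. Zinc finger genes, which had not passed before, were lower in that fit (median -0.06, adjusted p = 0.010). With an estimated correlation 0 lists passed in that fit, and each of these 7 had an adjusted p of 0.945. Of the 13 lists, proteasome subunits alone passed with each library left out in turn, and 3 remained past the threshold without unfixed b.

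Lists of protein quality control and energy metabolism were among them. Proteasome subunits had a median of -0.10 with 32 of 38 members lower (adjusted p = 8.25e-08; adjusted p = 0.599 with an estimated correlation), with Psmd11 at 395 ± 55.8 and 378 ± 10.8 CPM and Psmc6 at 135 ± 12.97 and 123 ± 7.69. Nuclear-encoded oxidative phosphorylation genes had a median of -0.10 with 69 of 83 lower (adjusted p = 8.25e-08; 0.599 as the adjusted p with an estimated correlation), with Atp5b at 351 ± 84.0 and 336 ± 31.4 CPM. Mitochondrial ribosomal proteins had a median of -0.09 with 49 of 75 lower (adjusted p = 3.80e-06; adjusted p = 0.599 with an estimated correlation); Mrps28 was at 107 ± 12.6 and 107 ± 12.9 CPM. Cytosolic ribosomal proteins had a median of -0.05 with 58 of 77 lower (adjusted p = 3.81e-04; adjusted p = 0.627 with an estimated correlation), with Rpl4 at 963 ± 125 and 872 ± 114 CPM. Heat shock genes and chaperones had a median of -0.10 with 19 of 20 lower (adjusted p = 3.81e-04; adjusted p = 0.599 with an estimated correlation), with Hsp90ab1 at 2865 ± 643 and 2644 ± 390 CPM. Unfolded protein response genes had a median of -0.10 with 14 of 18 lower (adjusted p = 0.0014; adjusted p = 0.599 with an estimated correlation), with the chaperone Hspa5 at 1117 ± 110 and 979 ± 115 CPM. Genes of the same abundance classes would give 22.4 lower proteasome subunits, 40.6 oxidative phosphorylation genes, 31.7 mitochondrial and 49.2 cytosolic ribosomal proteins, 13.7 heat shock genes and 10.5 unfolded protein response genes. Without unfixed b the median of mitochondrial ribosomal proteins was -0.021 (adjusted p = 0.435), that of cytosolic ones -0.015 (0.461), and the calls for oxidative phosphorylation (0.666), heat shock genes (0.057) and the unfolded protein response (0.717) were also lost. Without unfixed c the calls were lost for cytosolic ribosomal proteins (adjusted p = 0.099) and heat shock genes (0.110), and without fixed a for heat shock (0.184) and unfolded protein response genes (0.058).

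The other lists past the threshold held stress, signalling, matrix and cell identity genes. Immediate early genes had a median of -0.03 with 24 of 34 lower (adjusted p = 0.0098; adjusted p = 0.701 with an estimated correlation), with Fosb at 1277 ± 373 and 1223 ± 158 CPM and Myc at 694 ± 87.7 and 676 ± 56.5. Inflammatory and NF-kB genes had a median of -0.10 with 16 of 19 lower (adjusted p = 0.0022; adjusted p = 0.599 with an estimated correlation), with Nfkb1 at 1122 ± 132 and 1092 ± 189 CPM. Oxidative stress genes of the NRF2 pathway had a median of -0.06 with 15 of 17 lower (adjusted p = 0.0085; adjusted p = 0.599 with an estimated correlation), with Hmox1 at 784 ± 149 and 726 ± 129 CPM. Cell cycle genes had a median of -0.07 with 18 of 27 lower (adjusted p = 0.0098; adjusted p = 0.599 with an estimated correlation), with Mki67 at 26.7 ± 5.15 and 26.1 ± 3.70 CPM. Satellite cell markers had a median of -0.02 with 12 of 19 lower (adjusted p = 0.024; adjusted p = 0.627 with an estimated correlation), with Sdc4 at 1650 ± 80.1 and 1615 ± 236 CPM. Collagens and extracellular matrix genes had a median of -0.06 with 16 of 23 lower (adjusted p = 0.0081; adjusted p = 0.599 with an estimated correlation), with Hspg2 at 1482 ± 213 and 1461 ± 242 CPM. Endothelial markers had a median of -0.17 with 16 of 18 lower (adjusted p = 0.0022; adjusted p = 0.627 with an estimated correlation), with Pecam1 at 56.2 ± 14.8 and 49.7 ± 8.22 CPM. Genes of the same abundance classes would give 13.5 lower satellite cell markers, more than the 12 seen, 23.2 immediate early genes, 9.62 NF-kB genes, 11.7 NRF2 genes, 10.8 cell cycle genes, 15.2 extracellular matrix genes and 7.87 endothelial markers. With the trend on abundance removed the median of satellite cell markers was 0.011. Calls kept in direction were lost without unfixed b for NRF2 (adjusted p = 0.717), cell cycle (0.435) and extracellular matrix genes (0.057), without fixed b for NRF2 (0.405) and immediate early genes (0.975), and without fixed a for immediate early genes (0.356) and endothelial markers (0.059). They were also lost without unfixed a for NF-kB genes (adjusted p = 0.09994), without fixed c for cell cycle genes (0.130) and without unfixed c for immediate early genes (0.099) and satellite cell markers (0.352). The direction of the camera test turned without unfixed b for immediate early genes (median 0.017) and endothelial markers (0.051). It also turned without fixed b for satellite cell markers (0.019), NF-kB genes (0.023) and extracellular matrix genes, whose median stayed below 0 at -0.0097. The median alone turned without fixed a for heat shock genes (0.0040) and immediate early genes (0.031), without fixed b for immediate early genes (0.018) and without unfixed c for satellite cell markers (0.0065).

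The remaining lists did not pass in the test of all 6 libraries. Quiescence and Notch genes (adjusted p = 0.073, Notch2 at 467 ± 35.8 and 461 ± 25.3 CPM), p53 response genes (0.074, Cdkn1a at 104 ± 20.7 and 102 ± 16.99), housekeeping reference genes (0.092, Eef1a1 at 1083 ± 322 and 1084 ± 81.1) and zinc finger genes (0.091, Zfp407 at 336 ± 20.3 and 331 ± 18.9) had medians between -0.07 and 0.00. For zinc finger genes, nuclear-retained long noncoding RNAs and mature muscle fibre genes, the median was above 0 while the test pointed down, and for fibro-adipogenic and smooth muscle markers the mean was above 0 while the median and the test pointed down. Nuclear-retained long noncoding RNAs had an adjusted p of 0.206, with Neat1 at 6868 ± 832 and 6127 ± 1517 CPM. Myogenic differentiation genes (0.847, Musk at 391 ± 50.2 and 408 ± 87.1) and mature fibre genes (0.699, Neb at 37.7 ± 2.30 and 37.8 ± 4.16) gave no call either. Replication-dependent histones, with near-identical copies, had a median of 0.11 (adjusted p = 0.107), and small structural noncoding RNAs 0.11 (adjusted p = 0.567), with Rmrp at 658 ± 274 and 813 ± 513 CPM. Only 19 of 182 small structural RNA genes were measured. For the histones, fry's test of change in either direction gave an adjusted p of 0.019. Markers of other cell types gave adjusted p-values of 0.248 for fibro-adipogenic progenitors (Gsn at 380 ± 44.4 and 349 ± 53.7 CPM), 0.822 for immune cells (Cd74 at 15.6 ± 4.05 and 16.4 ± 1.58), 0.532 for smooth muscle and pericytes (Acta2 at 79.9 ± 9.12 and 74.8 ± 11.7), 0.832 for Schwann cells (Mbp at 28.4 ± 3.11 and 28.3 ± 1.74), 0.311 for tenocytes (Mkx at 6.97 ± 0.34 and 8.10 ± 1.24) and 0.699 for erythroid cells (Hbb-bs at 7.12 ± 5.13 and 7.54 ± 7.41). The 2 lists of mitochondrially encoded genes had 0 measured members.

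Some of these lists passed with the preset correlation under other settings fixed before the data were examined, none of which was run with an estimated correlation. Quiescence and Notch genes were lower with RLE size factors (adjusted p = 0.042), without the low-count filter (0.019), with a replicate block (0.038), without unfixed a (0.0020) and without fixed c (1.19e-05). The p53 response genes were lower with RLE size factors (adjusted p = 0.047), without the filter (0.027), with length and GC offsets (0.011), without unfixed a (0.049) and without fixed c (0.018). Zinc finger genes were lower without the filter (adjusted p = 0.030), with the offsets (0.038) and without unfixed b (0.026). Without fixed a the test pointed down (adjusted p = 0.025) while their median was above 0 (0.0020). Housekeeping reference genes were lower without the filter (adjusted p = 0.046) and without fixed c (0.019), as were nuclear-retained long noncoding RNAs without fixed c (7.24e-04) and smooth muscle markers without unfixed a (0.0071). Higher in fixed cells were histones after thinning (adjusted p = 0.022), without unfixed b (0.026) and without fixed b (6.60e-04), small structural RNAs after thinning (0.030), without unfixed a (0.022) and without fixed b (0.0049), and Schwann cell markers without unfixed b (0.026). Other calls came from settings chosen after the data were seen. Without unfixed b and fixed c, quiescence and Notch genes (adjusted p = 6.27e-05), nuclear-retained long noncoding RNAs (4.00e-05) and housekeeping reference genes (0.038) were lower. After subtraction of the long neuronal background, histones were higher (adjusted p = 0.038).

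**Figure D3:**
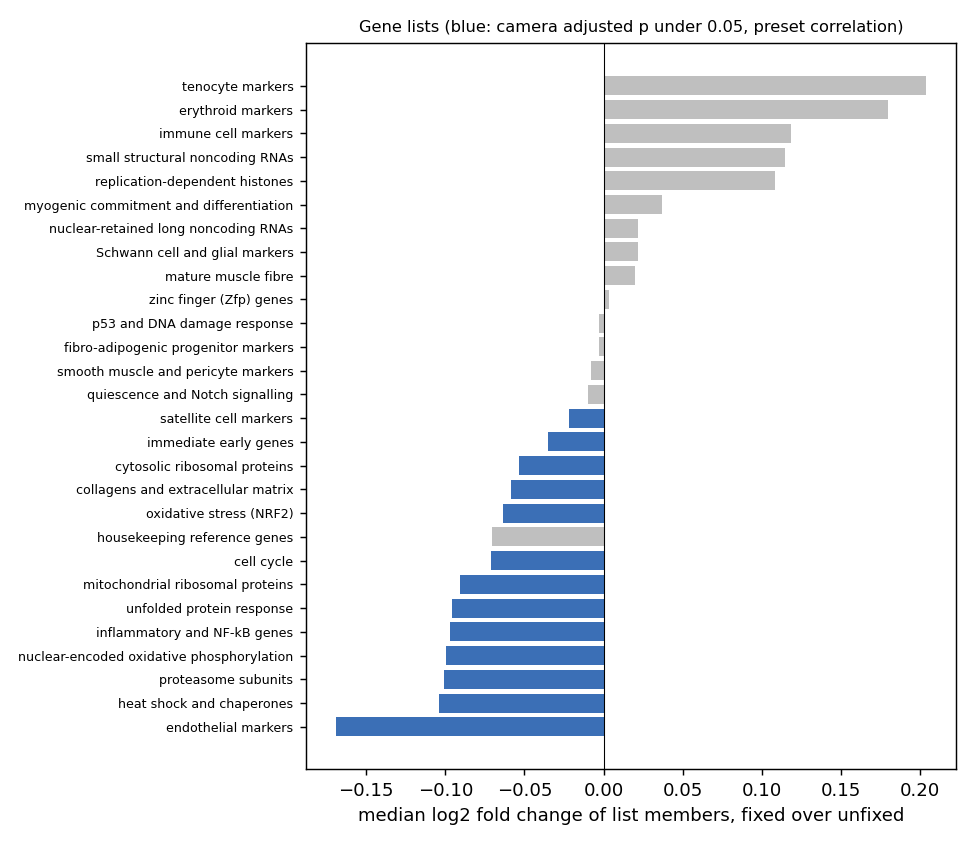
Median log2 fold change, fixed over unfixed, of the measured members of 28 gene lists; blue bars are lists past an adjusted p of 0.05 by camera with the preset correlation. The 13 blue bars lie between -0.17 and -0.02, and 0 lists passed with an estimated correlation.

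Protein-coding genes held 92.7% ± 0.057 of counts in unfixed and 92.4% ± 0.22 in fixed cells, and ribozyme RNAs, which include Rpph1 and Rmrp, held 0.185% ± 0.0086 and 0.249% ± 0.037. For both classes the libraries of the groups did not overlap (exact permutation p = 0.1, the smallest possible with 3 against 3, so that chance alone separates 10% of such classes). Ribozyme shares ran from 0.179% to 0.195% in unfixed and from 0.210% to 0.285% in fixed libraries, and protein-coding shares from 92.67% to 92.78% and from 92.19% to 92.62%. No class could pass the threshold in this design, and the lowest adjusted p over 18 classes was 0.72, so the test does not show equal shares either. Cytosolic ribosomal protein genes held 0.859% ± 0.091 and 0.813% ± 0.040 (exact p = 0.4), nuclear-retained long noncoding RNAs 2.60% ± 0.19 and 2.40% ± 0.077 (exact p = 0.2), and small structural RNAs 0.301% ± 0.059 and 0.386% ± 0.077 (exact p = 0.2). Of 182 small structural RNA genes, 160 were at 0 in every library, which for a gene inside another says nothing about its expression. Shares of counts, that of protein-coding genes with its possible intronic reads included, thus depend on how reads were counted. The 10 most abundant genes of each library held 7.96% ± 0.49 and 9.16% ± 0.95 (exact p = 0.2), with the highest share in fixed c at 10.26%. Il1rapl1 alone held 709387 of 40154441 counts in fixed c and 888429 of 76799920 in fixed b. In unfixed a, b and c it had 4894, 8896 and 1671 counts, so part of the higher share in fixed b and c was this gene. With 1 library left out, the difference in the share of the 10 most abundant genes ran from 0.65 (without fixed c) to 1.53 percentage points, against 1.20 over all libraries.

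At equal depth, 26025 ± 1722 genes had at least 1 count in unfixed and 26895 ± 1878 in fixed cells, a difference within the spread of the libraries (exact permutation p = 0.5). Fixed b had 28307 and fixed c 24763 such genes, and unfixed a 27361 and unfixed b 24082. The 6 libraries stood in the same order by counts per kb over chemosensory receptor genes, which mostly have no known use in muscle. Before thinning, 119 of these 1414 receptor genes were at 0 in all 6 libraries. A single count therefore does not show that a gene is expressed, and detection may follow background as well as transcripts. Pearson correlations of log2(CPM + 1) across genes averaged 0.991 within groups and 0.992 between groups (exact permutation p = 0.9), and the group means correlated at 0.998. Genes are not independent replicates in these correlations.

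Over all 21717 genes the log2 fold change had a Spearman correlation of -0.412 with mean abundance, from a median log2 fold change of 0.31 with 75.1% of genes higher under 1 CPM to -0.04 with 26.4% higher at 100 CPM or more. Without fixed b that correlation was -0.144 and without unfixed b -0.165. Across 21652 genes with an annotated length, the log2 fold change had a Spearman correlation of -0.127 with exon length, 0.157 with gene body length and -0.052 with GC content. The median log2 fold change was 0.16 over the 4332 genes with the shortest exon length and 0.01 over the 4330 with the longest. Libraries of the same group differed in sign: for gene body length the values were 0.103 for fixed a, 0.168 for fixed b and -0.104 for fixed c, and unfixed b against the other unfixed libraries gave -0.236. With a mean CPM of at least 5, the correlation with exon length was 0.106 and that with gene body length 0.388. Without unfixed b the correlation with gene body length was -0.038.

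The first principal component of log2 CPM held 56.4% of the variance and placed unfixed b at 84.0 and fixed c at 50.1, and the other libraries between -60.4 and -8.06. Chemosensory receptor genes, such as olfactory receptors, had 0.0089 counts per kb of gene body per 1e6 counts in unfixed b and 0.0097 in fixed c. The other libraries had 0.0144 to 0.0196, the highest in fixed b. The lower medians of the 13 lists and the length correlations were measured across these same libraries.

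**Figure D4:**
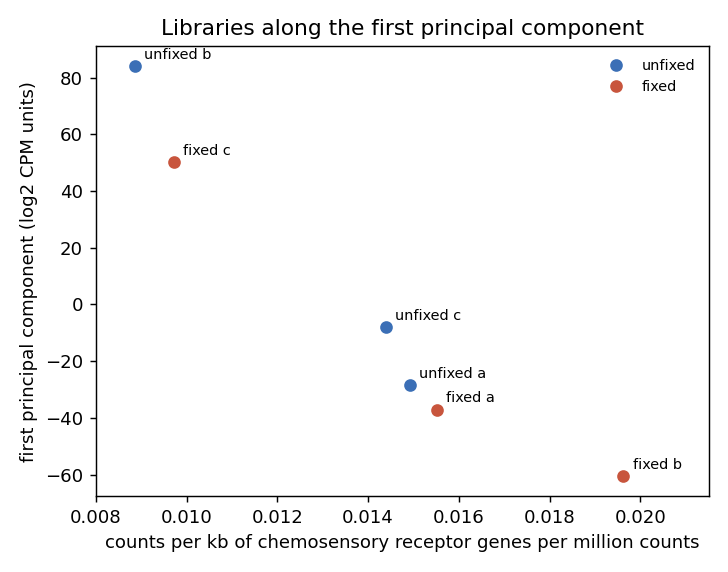
Position of each library on the first principal component (y axis, log2 CPM units) against counts per kb of chemosensory receptor genes per 1e6 counts (x axis), with unfixed libraries in blue and fixed in red. Unfixed b (84.0) and fixed c (50.1) stand at the upper left with 0.0089 and 0.0097 counts per kb, and fixed b at the lower right with 0.0196.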

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

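Joint removal of unfixed b and fixed c, both background subtractions and removal of the trend on abundance were chosen after the data were seen; all other alternatives were fixed before. With edgeR, 0 genes were called with total-count scaling (137 at an unadjusted p under 0.05), without the low-count filter (517), at a mean CPM of at least 5 (42), against a 1.5-fold null (66) and after subtraction of the chemosensory background (179), and limma-voom also called 0 (317). DESeq2 called 4, and 12 were called without unfixed b and fixed c; the cause was not tested. Leaving out 1 library gave 0 calls (without unfixed a) to 1, and without fixed a the gene called was Il1rapl1. The count within 2-fold ran from 11518 to 14715 with 1 library left out, and 8212 genes passed the narrower 1.5-fold bound.

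With the letters as a replicate block, 0 genes were called (173 at an unadjusted p under 0.05). The labels do not pair the samples, same-letter libraries deviated from their group means with correlations of 0.383, -0.429 and -0.195, and not every library correlated best with its own letter.

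List calls numbered 13. They numbered 17 without the low-count filter, 15 with RLE size factors and 5 at a mean CPM of at least 5. After subtraction of the long neuronal background they numbered 7, among them replication-dependent histones, which were higher in fixed cells and not among the 13. With the trend on abundance removed they numbered 7 (6 of the 13 and zinc finger genes). They numbered 0 with an estimated correlation, 0 by fry, and 6 (without unfixed b) to 16 with 1 library left out. Over the 13 lists the estimated correlation ran from 0.19 (cell cycle genes) to 0.79 (endothelial markers), above the preset 0.01. The preset-correlation p-values do not allow for members that vary together that much. The cause of the other differences was not tested. RLE size factors moved the median over all genes from 0.044 to 0.0052, and with it that of satellite cell markers from -0.022 to -0.062 and that of cytosolic ribosomal proteins from -0.054 to -0.095. Over the leave-one-out fits the medians ran from -0.185 to 0.019 for satellite cell markers, -0.195 to 0.031 for immediate early genes, -0.203 to 0.023 for NF-kB genes, -0.169 to -0.0097 for extracellular matrix genes, -0.354 to 0.051 for endothelial markers, -0.266 to 0.0040 (without fixed a) for heat shock genes, -0.181 to -0.057 for cell cycle genes and, with the highest value without unfixed b, -0.240 to -0.0053 for oxidative phosphorylation, -0.211 to -0.0079 for the unfolded protein response, -0.151 to -0.021 for mitochondrial and -0.203 to -0.015 for cytosolic ribosomal proteins, -0.139 to -0.018 for NRF2 genes and -0.182 to -0.061 for proteasome subunits. Of 556 list values under alternatives, 414 kept direction and side of the threshold, and of 2472 values of named genes 2191 did; 268 of the latter changed sign without a call on either side.

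The ribozyme share differed by 0.0030 percentage points once small structural RNAs were removed, which takes out Rpph1 and Rmrp. At a mean CPM of at least 5, the correlation of fold change was 0.106 with exon length and 0.388 with gene body length. With 1 library left out it ran from -0.038 to 0.173 for gene body length and from -0.160 to 0.168 for GC content; the cause was not tested. Other shares and detection moved by less than the larger group SD, and library correlations by less than the SD over pairs of libraries. With 1 library left out, the difference in genes detected still ran from -102 (without unfixed b) to 1935, and the difference in share turned sign for oxidative phosphorylation, histones, rRNA, snoRNA and pseudogenes. Depth limits the rarest genes in part: of 3003 with a mean CPM under 1 that were tested in both fits, 444 lay within 2-fold and 201 after thinning. Counting error alone would give all 6168 such genes a median standard error of 0.28, where 0.58 was measured.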

Other observations

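Tests of the first principal component against sequencing depth and fixation, and of the neighbours of Trim71 alone, were chosen after the result was seen, and so were the fits with a background or the trend on abundance removed. Left without unfixed b and fixed c, the 12 genes that edgeR called included Zc3h7a, a zinc finger gene, named here after its values were seen. In that fit its log2 fold change was 2.01 (adjusted p = 2.02e-16), with 1910 and 1666 CPM in unfixed a and c and 6963 and 7485 CPM in fixed a and b. Over all 6 libraries Zc3h7a was at 3526 ± 3193 CPM in unfixed and 9855 ± 4648 in fixed cells and was not called (adjusted p = 1.00). Sspn was also among the 12 (log2 fold change 1.07, adjusted p = 0.0048). Most of the others were rare, such as Scand1 at 1.47 to 3.83 CPM over the libraries kept.

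The 6 libraries differed most along a component that set unfixed b and fixed c apart from the others. Sequencing depth is argued against, since with every library thinned to 20709602 counts the component kept its order of the libraries (Spearman rho of 1), while fixation stays open: the component is named by 1 library of each group, so the 1 fixed library out of order tests nothing, and fixed a and b lay lowest at -37.1 and -60.4. A uniform background such as genomic DNA may account for it: counts per kb over 1414 chemosensory receptor genes, mostly without known use in muscle, ranked the libraries exactly along it, with rho = -1 (exact permutation p = 0.0028; Pearson r = -0.967, p = 0.0014) and the same rho without Olfr16, a receptor known from muscle regeneration. The component was drawn from the same libraries, and 6168 of its 21717 genes had a mean CPM under 1. The ranking therefore does not tell a background from another difference that rare genes share. The slope of log counts on log gene body length over the chemosensory and 30 long neuronal genes was 0.960, but that on exon length was 0.987. In addition, 2 libraries stand apart, so that r rests largely on them. The other 4 are too few for a correlation of their own, and r without fixed b and unfixed b (-0.988) still holds fixed c. Against a uniform background, the median densities of both lists were 3.68-fold to 4.61-fold apart in 3 libraries, beyond the 3-fold bound set before the test. In the other 3 the chemosensory median was 0, so the bound was met in no library. The chemosensory genes held a median of 10 counts over all 6 libraries, so the medians are poor measures. Pooled densities, which were not part of the test set before, were 2.13-fold to 2.34-fold apart. Whether the background is uniform stays open.

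The lower medians of the 13 lists in fixed cells may rest in part on that background. After its subtraction by the long neuronal genes, 7 lists passed where 13 had, a count between the bounds set for and against it. The subtraction removed 0.91% (unfixed b) to 3.64% (fixed b) of the counts of a library, and the groups overlapped. Among the 7 lists were replication-dependent histones, which were higher in fixed cells (median 0.13, camera adjusted p = 0.038) and not among the 13. The background as an explanation stays open. A trend of fold change with abundance over all genes may also account for part. Once it was removed, 6 of the 13 lists were still lower with the preset correlation, again between the bounds, so this too stays open. In that fit 0 lists passed with an estimated correlation. Of the 10 splits of the 6 libraries into 3 and 3, 6, the real one included, gave at least as many lists, with 13 in the real split and 18 the highest other. Those 10 splits are too few for a share under 0.05. The counts of the other splits ran from 8 to 18, so the 13 lists of the real split were not unusual among groupings of these libraries.

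For Trim71 and Il1rapl1, a uniform background is argued against as the source of the higher levels, since the highest ratios of their counts to it were 137 for Trim71 in unfixed b and 1143 for Il1rapl1 in fixed c. In the lower group the ratios were 2.89 to 4.10 for Trim71 and 2.38 to 12.5 for Il1rapl1, so part of those levels may be background: after its subtraction by the long neuronal genes the log2 fold change of Trim71 was -4.29 against -3.79, and the log2 fold change of Il1rapl1 was 7.07 against 6.68. A change of the whole region is argued against for Trim71, whose 14 tested neighbours within 500 kb had a median log2 fold change of 0.033, and stays open for Il1rapl1, whose single tested neighbour had 0.52. No biological explanation was tested beyond the grouping itself.

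The 10 splits are likewise too few for a share under 0.05 for the other counts. The real split called 1 gene, the highest other 1, and 2 splits, the real one included, gave as many. The real split placed 13393 genes within 2-fold, the highest other 13634, and 6 splits, again with the real one, gave as many. The split of unfixed a, fixed a and fixed b against the rest gave the most genes at an unadjusted p under 0.05, 5825 against 200 in the real one, and 0 called genes. It holds the 3 libraries lowest on the first principal component and so restates that pattern.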
